A study of Mus musculus with 12 samples.

How the data were processed

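Muscle RNA of 12 mice was analysed, 4 each of NTV, TV and TL. Per the labels' protocols, the libraries were made from poly(A) mRNA with random hexamer priming; whether reads were counted by strand is not stated. The submitters' processing notes name HISAT2 2.05, featureCounts 1.5.0-p3, DESeq2 and the mouse build mm10, without giving the role of each in the deposited values. The values used are FPKM, which the authors deposited as 1 table of 54532 genes by 12 libraries, so alignment, counting and scaling were done before the files were analysed here. The gene length in bases, which the authors deposited in the same table, was used only to recover reads. No column of samples was left out.

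In every library, FPKM times gene length was a whole multiple of 1 step for 100% of genes, within a tolerance of 0.1 read, so the reads behind each value were recovered. The scale between libraries implied by these steps equalled median-of-ratios size factors to a relative difference of 8.17e-12, apart from a common factor of 1.01. The FPKM values are therefore scaled by such factors and not by the total of each library. A table scaled in this way assumes that most genes do not differ between groups. Pairs of libraries of the same group differed by a chi-square per degree of freedom of at least 16.4 over 18 pairs, so over all genes the libraries of a group differed by more than counting error. Limits allowed by 0 reads were taken at 3 reads and cover counting error only.

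Changes were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5), with 1 mean per group, all 12 libraries in the fit, a mean-variance trend and Benjamini-Hochberg adjustment over the 12754 genes with a mean FPKM of at least 0.5. A gene was called at an adjusted p under 0.05. Before the data were examined, 41 gene lists were fixed, of which 37 had at least 5 tested members; 894 of 895 symbols were found. Lists were tested with camera at a preset correlation between genes of 0.01. Some genes stand in more than 1 list, so list results are not independent. Members called over all genes and members called when adjusted over the list alone were counted beside each. An estimated correlation and fry were set as further tests with the lists, and an exact permutation of the library means of each list was added after the data were seen. The 3 comparisons were TV against NTV, TL against TV and TL against NTV.

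Genes are named by a rule fixed with the lists. It takes the 6 largest rises and the 6 largest falls among called protein-coding genes with a mean FPKM of at least 1 and no overlap between groups, and up to 3 called members of each called list, or 2 members as values where none was called. For TL against NTV it takes 0.5 times as many. It always takes Trim63, Fbxo32, Mstn, Foxo1, Pdk4, Cebpd, Mt1, Mt2, Fkbp5, Myh1, Myh2, Myh4, Myh7, Ucp3, Ppargc1a, Ret, Gfral and Gdf15. The text gives a selection of the list members where a list has more. Scd1, Fasn, Ucp1, Gdnf and Ighm are exceptions, chosen after the values were seen. Gene positions come from the deposited table; 54409 of its gene IDs were in the reference annotation, 53499 with the same coordinates.

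Before they were run on the real values, the tests were tried on simulated data with known changes. Gene means, spreads and library scales came from the real libraries. For TV against NTV, 63 of 96 2-fold and 82 of 95 4-fold changes were recovered, with 11 false calls. A raised list was called and 0 of 30 unchanged lists were. Genes were drawn independently with 1 spread for all groups, so the trial does not cover correlated lists or unequal spread. Other settings tried were other pseudocounts and filters, other scalings between libraries (an equal total, quantiles, an equal total without mitochondrial and the 50 most abundant genes, and median-of-ratios factors computed again on the tested genes alone), a fit without the trend, a robust fit, library weights, only the 2 groups compared, the replicate number as a block, and each library left out in turn. Added after the data were seen were voom on the recovered reads, leaving out libraries with Ucp1 above 2 FPKM, and the mean of the adipocyte markers as a covariate. For comparisons that share libraries, unchanged groups were simulated 100 times, and the shared libraries were divided so that each comparison had its own. Figures were drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.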

Results

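RNA was sequenced from the gastrocnemius, the large calf muscle, of female ICR SCID mice. This immunodeficient strain usually lacks mature T and B cells. The labels give 3 groups of 4 libraries each, stated as biological replicates. NTV mice carried no tumour and received vehicle. TV mice carried a subcutaneous tumour of HT1080, a human fibrosarcoma cell line, and received vehicle. TL mice carried the same tumour and received selpercatinib, an inhibitor of the receptor tyrosine kinase RET, by oral gavage at 30 mg/kg once daily for 19 days. The series concerns selpercatinib and cancer cachexia, the loss of muscle and fat that accompanies some tumours. RET is best known as the receptor for ligands of the GDNF family and, together with GFRAL, for the hormone GDF15.

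Depth ranged from 14939830 to 23580603 reads assigned to genes per library, both extremes in TV. Of the 54532 genes listed, 12754 had a mean FPKM of at least 0.5 and were tested. Levels are FPKM as mean ± SD (n = 4 per group). Changes are log2 differences of FPKM + 0.5, as estimate ± SE from limma. The added constant understates the change of weakly expressed genes. Each SE rests on 1 spread per gene, shared by all 3 groups. Reads of the mitochondrial genome made up 12.4% ± 0.801 (SD, n = 4) of all reads in NTV, 6.53% ± 1.08 in TV and 9.17% ± 3.67 in TL. Principal component 1 held 34.5% of the variance. It placed the NTV libraries between -36.7 and -25.6, the TL libraries between -10.4 and 27.6, and the TV libraries between 14.2 and 39.1. On component 2, with 12.8% of the variance, TL replicates 1 and 5 stood apart from the other libraries at -31.9 and -32.6.

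**Figure D1:**
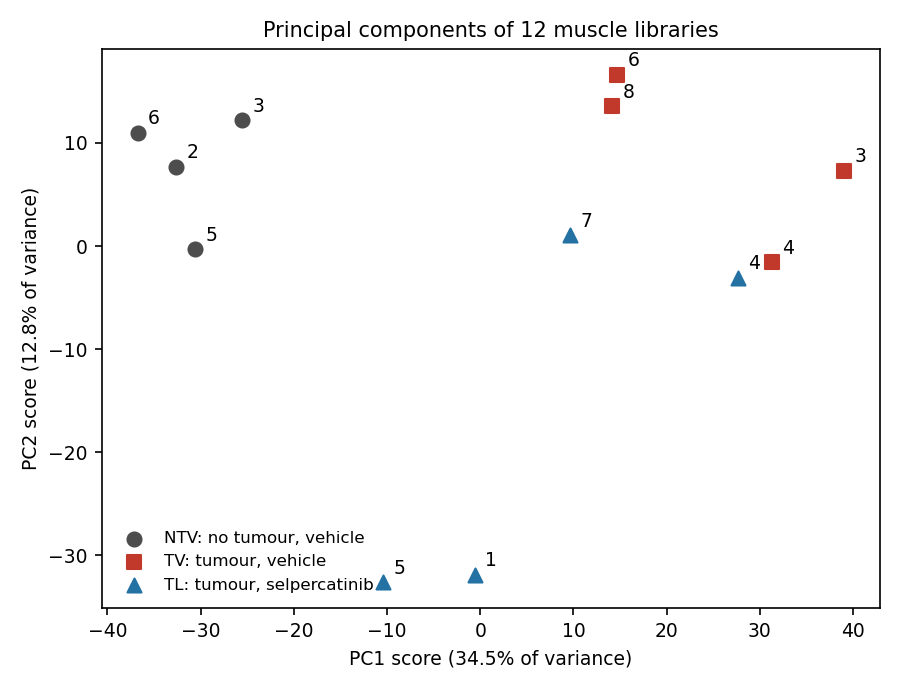
Scores of the 12 muscle libraries on principal components 1 (x axis, 34.5% of the variance) and 2 (y axis, 12.8%) of log2(FPKM + 0.5), with the replicate number beside each point. The NTV libraries lie at component 1 scores from -36.7 to -25.6 and the TV libraries from 14.2 to 39.1, while TL replicates 1 and 5 lie lowest on component 2.

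The comparison of TV with NTV asked which muscle transcripts differed with the tumour in vehicle-treated mice. Mt1, a metallothionein that binds metals and is induced by stress and glucocorticoids, rose from 20.7 ± 13.5 to 308 ± 178 FPKM (log2 change 3.96 ± 0.68, adjusted p = 0.00264). Trim63, which encodes the muscle ubiquitin ligase MuRF1, rose from 79.6 ± 26.1 to 405 ± 295 FPKM (2.12 ± 0.56, adjusted p = 0.0183). Fbxo32, which encodes the ligase atrogin-1, rose from 46.6 ± 6.52 to 187 ± 106 FPKM (1.79 ± 0.54, adjusted p = 0.0319). Col1a1, a chain of type I collagen, fell from 25.8 ± 10.9 to 2.16 ± 1.07 FPKM (-3.33 ± 0.40, adjusted p = 0.000898). Kera, which encodes the tendon and corneal proteoglycan keratocan, fell from 11.5 ± 6.16 to 0.24 ± 0.197 FPKM (-3.92 ± 0.47). Fabp3, the fatty acid binding protein of heart and oxidative muscle, fell from 784 ± 118 to 175 ± 58.4 FPKM (-2.22 ± 0.31). Among 12754 genes, limma called 3217 at an adjusted p under 0.05, 1755 higher and 1462 lower in TV, and 555 of them changed by at least 2-fold. For 27.1% of all tested genes the 4 TV values did not overlap the 4 NTV values, where chance gives 2.86%. The call of Trim63 ended without TV replicate 3 (adjusted p = 0.0501), and that of Fbxo32 ended when any 1 of NTV replicates 2, 3, 5 and 6 and TV replicates 3 and 4 was left out (up to 0.0879). Fbxo32 was not called with no filter on low values either.

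Of the protein-coding genes with separated groups, the other large rises were those of Mt2 (3.33 ± 0.89, adjusted p = 0.0185), Ddit4 (3.22 ± 0.95, adjusted p = 0.0287), an inhibitor of mTORC1 signalling, and Ctxn3 (3.06 ± 0.58). Others were those of Tmem100 (46.2 ± 14.2 against 6.15 ± 2.49 FPKM) and Serpina3n, a secreted protease inhibitor (14.6 ± 11.8 against 1.22 ± 0.518 FPKM). The other large falls were those of Actc1, the cardiac form of sarcomeric actin (8.78 ± 5.54 against 101 ± 46.4 FPKM), BC048679 (-3.47 ± 0.57) and Mfap4, a microfibril protein (-3.13 ± 0.32). Tnmd, the tendon marker tenomodulin, fell as well (-3.10 ± 0.43). The call of Mt2 ended without NTV replicate 2 or 6 or TV replicate 3 or 4 (adjusted p up to 0.0549), and that of Ddit4 without NTV replicate 2 or 6 or TV replicate 3, 4 or 6 (up to 0.0806). With no filter the call of Ddit4 ended, and with voom on recovered reads that of Mt2.

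Of 25 genes that respond to FoxO transcription factors or glucocorticoids, 19 rose, none fell and 6 were not called, with a median log2 change of 1.38 (22 and 0 adjusted over the list alone; adjusted p = 0.446 with an estimated correlation). They included Eif4ebp1, a repressor of cap-dependent translation (14.9 ± 5.5 to 99.7 ± 50.7 FPKM) and Glul, glutamine synthetase (85.9 ± 18.5 to 304 ± 91.1 FPKM). Others were Foxo3 (1.25 ± 0.17), Cebpd (2.70 ± 0.69, adjusted p = 0.0154) and Fkbp5, a glucocorticoid-induced co-chaperone (2.41 ± 0.47, adjusted p = 0.00481). Of 32 proteasome subunit genes, 13 rose and 1 fell, with a median of 0.31 (17 and 1 adjusted over the list alone; adjusted p = 0.573 with an estimated correlation). Among them were Psmd8 (44.3 ± 4.64 to 102 ± 18.5 FPKM), Psmd4 (1.06 ± 0.20) and Psma7 (0.86 ± 0.19). Of 27 autophagy and lysosome genes, 12 rose and 1 fell, with a median of 0.30 (15 and 2 adjusted over the list alone; adjusted p = 0.448 with an estimated correlation). Ctsl, a lysosomal cysteine protease, and Sqstm1, the autophagy receptor p62, rose by 1.12 ± 0.14 and 1.09 ± 0.14, while Trp53inp2, which takes part in autophagosome formation, fell (-1.36 ± 0.18). Of 18 atrophy ubiquitin ligase genes, 7 rose and 1 fell, with a median of 0.35 (7 and 1 adjusted over the list alone; adjusted p = 0.575 with an estimated correlation). These included the polyubiquitin gene Ubb (0.89 ± 0.15), Ube4a (1.31 ± 0.24) and Fbxo31 (0.99 ± 0.19). This list was no longer called by camera without NTV replicate 5 or TV replicate 3 or 4 (adjusted p up to 0.0876), and its median was 0.21 without TV replicate 4 and 0.53 without TV replicate 8. Neither was it called with a mean FPKM of at least 1, with quantile normalization or without the libraries with Ucp1 above 2 FPKM.

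**Figure D2:**
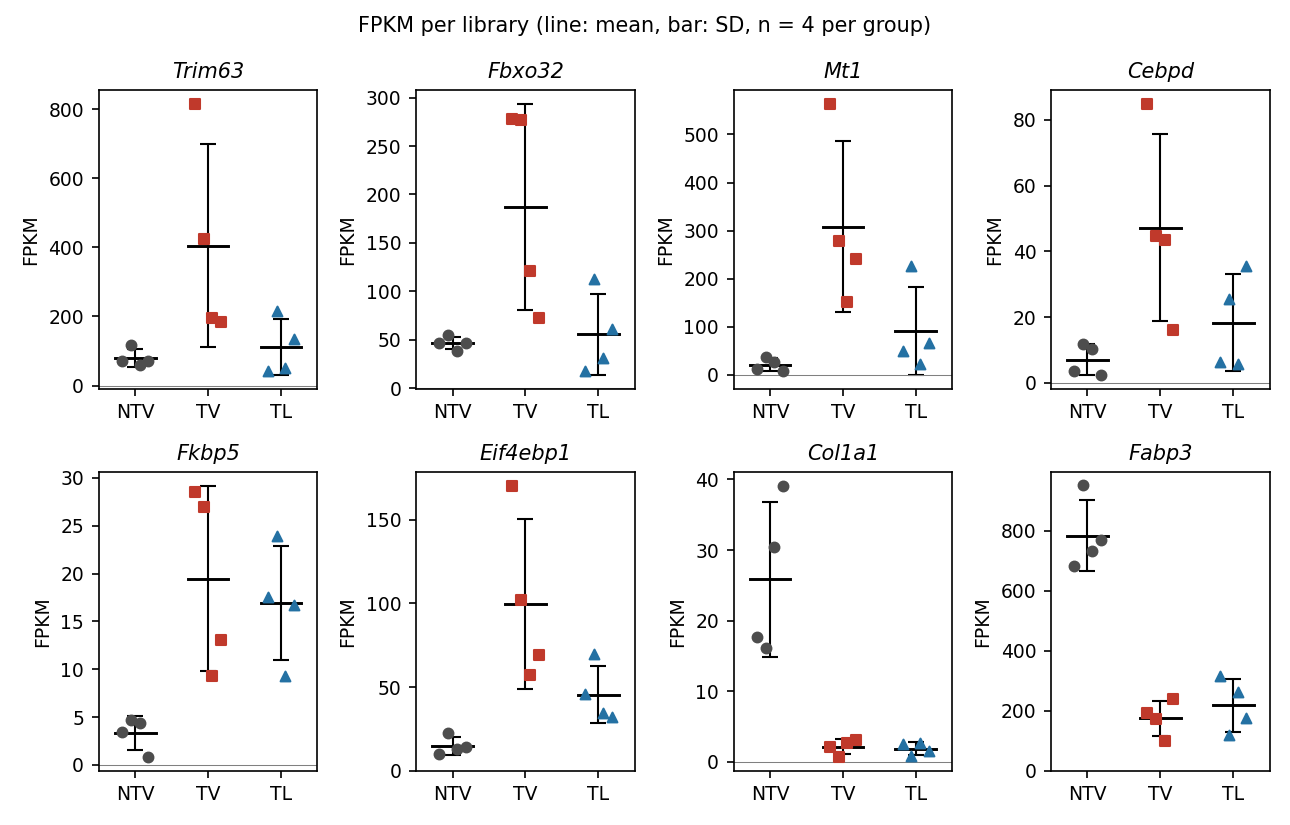
FPKM (y axis) of 8 genes in each library of NTV, TV and TL (x axis), with the mean as a line and the SD as a bar (n = 4 per group). Trim63, Fbxo32, Mt1, Cebpd, Fkbp5 and Eif4ebp1 have higher means in TV than in NTV, while Col1a1 averages 25.8 FPKM in NTV and 2.16 in TV, and Fabp3 averages 784 and 175.

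Cytosolic ribosomal protein genes moved together: 58 of 73 rose, none fell and 15 were not called, with a median of 0.72 (64 and 0 adjusted over the list alone; adjusted p = 0.446 with an estimated correlation). Rpl4 rose from 292 ± 30.4 to 568 ± 19.5 FPKM, and Rps12 rose by 0.87 ± 0.12; 27 of the 73 have 3 to 24 pseudogenes annotated under their name, with which reads can be shared, and 34 have 0 to 1. Of 24 ribosome biogenesis genes, 8 rose and 0 fell, with a median of 0.27 (9 and 0 adjusted over the list alone; adjusted p = 0.446 with an estimated correlation). Examples were the nucleolar genes Ncl (0.59 ± 0.10), Gnl3 (0.56 ± 0.13) and Mybbp1a (0.40 ± 0.09).

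Of 18 acute phase and IL-6 family genes, 11 rose and 0 fell, with a median of 1.13 (11 and 0 adjusted over the list alone; adjusted p = 0.446 with an estimated correlation). They included Stat3, the transcription factor downstream of IL-6 receptors (8.13 ± 0.632 to 22.5 ± 4.23 FPKM, adjusted p = 0.00095), the receptor chain Il6ra (2.62 ± 0.38) and the kinase Pim1 (2.18 ± 0.33). Of 20 immediate early genes, 9 rose and 0 fell, with a median of 1.16 (10 and 0 adjusted over the list alone; adjusted p = 0.565 with an estimated correlation). Called members included Maff (2.45 ± 0.50), Junb (1.92 ± 0.44) and Fosl2, whose call ended without NTV replicate 6 (adjusted p = 0.0502). Of 19 insulin and IGF signalling genes, 8 rose and 0 fell, with a median of 0.30 (10 and 2 adjusted over the list alone; adjusted p = 0.446 with an estimated correlation). Among them were the receptor Igf1r (1.13 ± 0.20) and the kinase Akt1 (0.66 ± 0.16). Foxo1, Irs2 and Eif4ebp1 of this list also belong to the FoxO and glucocorticoid responsive list, so the results of these lists overlap. Of 18 circadian clock genes, 5 rose and 0 fell, with a median of 0.46 (8 and 0 adjusted over the list alone; adjusted p = 0.446 with an estimated correlation). These included Cry2 (1.58 ± 0.24) and Ciart (1.59 ± 0.42). Since no time of sampling is given, a difference in it between TV and NTV cannot be told apart from the tumour. The insulin list was no longer called without NTV replicate 3 or TV replicate 3 (adjusted p up to 0.0556), and the clock list without TV replicate 6 (0.0606). The clock list was also not called with a mean FPKM of at least 1.

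Of 74 oxidative phosphorylation genes of the nucleus, 31 fell and 1 rose, with a median of -0.43 (43 and 1 adjusted over the list alone; adjusted p = 0.573 with an estimated correlation). Cytochrome c, encoded by Cycs, fell from 116 ± 8.22 to 57.1 ± 6.31 FPKM, and the complex I genes Ndufb5 and Ndufs1 changed by -0.71 ± 0.12 and -0.93 ± 0.16. Of 22 tricarboxylic acid cycle genes, 17 fell and 0 rose, with a median of -0.57 (18 and 0 adjusted over the list alone; adjusted p = 0.497 with an estimated correlation). Examples were Dlat (-1.04 ± 0.17) and Dlst (-0.78 ± 0.12), subunits of the pyruvate and oxoglutarate dehydrogenase complexes. Of 34 fatty acid oxidation genes, 16 fell and 0 rose, with a median of -0.54 (16 and 0 adjusted over the list alone; adjusted p = 0.579 with an estimated correlation). Called members included the carnitine palmitoyltransferase Cpt2 (-0.95 ± 0.19) and the electron transfer dehydrogenase Etfdh (-0.81 ± 0.17). Of 13 genes encoded by the mitochondrial genome, 5 fell and 0 rose, with a median of -0.78 (9 and 0 adjusted over the list alone; adjusted p = 0.573 with an estimated correlation). The ATP synthase subunit mt-Atp6 changed by -2.05 ± 0.21, and the complex I subunits mt-Nd1 and mt-Nd6 by -0.81 ± 0.24 and -0.94 ± 0.29. The call of mt-Nd1 ended when any 1 of the 4 NTV libraries or TV replicate 3 was left out (adjusted p up to 0.0714), and that of mt-Nd6 when any 1 of these or TV replicate 6 or 8 was (up to 0.0889). Both calls ended with no filter. Whether reads were counted by strand is not stated, so RNA of the opposite strand may be counted under these mitochondrial genes.

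Of 30 extracellular matrix genes, 21 fell and 1 rose, with a median of -1.24 (25 and 1 adjusted over the list alone; adjusted p = 0.446 with an estimated correlation); Col3a1 and Col1a2 changed by -2.97 ± 0.40 and -2.91 ± 0.37. Of 9 tenocyte marker genes, 8 fell and 0 rose, with a median of -2.08 (8 and 1 adjusted over the list alone; adjusted p = 0.446 with an estimated correlation). Cilp2 was 1 of them (-2.08 ± 0.31). Of 12 markers of fibro-adipogenic progenitors, the mesenchymal stromal cells of muscle, 5 fell and 0 rose, with a median of -0.62 (5 and 0 adjusted over the list alone; adjusted p = 0.573 with an estimated correlation). These included Serpinf1 (-1.75 ± 0.30), Cd34 (-0.90 ± 0.17) and Dpt (-1.29 ± 0.30). Of 15 endothelial markers, 2 fell, namely the receptor Kdr (-1.39 ± 0.20) and the cadherin Cdh5 (-0.69 ± 0.16), with a median of -0.15 (2 and 0 adjusted over the list alone; adjusted p = 0.662 with an estimated correlation). The endothelial list was no longer called without NTV replicate 3 or 5 or TV replicate 4 or 6 (adjusted p up to 0.195); its median was -0.093 without NTV replicate 5 and -0.30 without TV replicate 8. The endothelial call also ended when libraries were rescaled to an equal total or by median-of-ratios on the tested genes. The same held without mitochondrial and the 50 most abundant genes, without the trend and without the libraries with Ucp1 above 2 FPKM.

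Of 16 heat shock genes, 4 fell in TV against NTV and 0 rose, with a median of -0.32 (4 and 0 adjusted over the list alone; adjusted p = 0.573 with an estimated correlation). Examples were the mitochondrial chaperonin Hspd1 (-0.73 ± 0.12), Hspa4l (-0.92 ± 0.17) and Chordc1 (-0.61 ± 0.08). Of 28 interferon responsive genes, only Psmb9 (-0.56 ± 0.14), an immunoproteasome subunit, and Ifit3 (-0.84 ± 0.28, adjusted p = 0.0477) fell, with a median of -0.24 (0 and 0 adjusted over the list alone; adjusted p = 0.662 with an estimated correlation). The heat shock list was no longer called without TV replicate 4 (adjusted p = 0.0785), its median was -0.18 without TV replicate 6, and the interferon list was not called without NTV replicate 5 or 6 or TV replicate 3, 4 or 8 (up to 0.112). Ifit3 has a near-identical copy, Ifit3b, and its call ended when any 1 of the 4 NTV libraries or TV replicate 3, 4 or 8 was left out (up to 0.12). The interferon call also ended with a mean FPKM of at least 1, median-of-ratios on the tested genes, quantile normalization, and without mitochondrial and the 50 most abundant genes. That of Ifit3 ended with no filter, without the trend, in a robust fit and with only the 2 groups compared. Both ended with the adipocyte covariate and without the libraries with Ucp1 above 2 FPKM.

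Camera called 20 of 37 lists, 10 higher and 10 lower in TV, with a preset correlation of 0.01 between genes. None was called with an estimated correlation (0 lists at an unadjusted p under 0.05), and fry, which tests a list by itself, called 18, of which 17 were among the 20 and the other was fast fibre (adjusted p = 0.0457). Fatty acid oxidation, interferon responsive and endothelial genes were not called by fry (adjusted p = 0.0808, 0.192 and 0.155). An exact two-sided permutation of the library means of each list reached its smallest possible p of 0.0286 in 16 lists, with a smallest adjusted p of 0.0661. Without the NTV library that expressed Ucp1, NTV replicate 5, camera did not call the atrophy ligase, interferon and endothelial lists. Of the lists not called, adipocyte markers came closest (adjusted p = 0.0818, median 0.54), with the lipid droplet gene Plin4 called (1.42 ± 0.34) and Retn not called (1.64 ± 0.62, adjusted p = 0.0717; called with library weights, with only the 2 groups compared and without the libraries with Ucp1 above 2 FPKM). Fast fibre contractile genes followed (adjusted p = 0.132, median 0.33): 5 of 18 rose, including the myosin kinase Mylk2 (233 ± 53.3 to 749 ± 71.3 FPKM) and the fast fibre actinin Actn3 (1.29 ± 0.19). Adjusted p was 0.154 for denervation responsive genes and for fatty acid and sterol synthesis, 0.193 for sarcomere and Z-disc genes and 0.226 for smooth muscle and pericyte markers. Higher values were 0.322 for the integrated stress response and 0.341 for myostatin, activin and BMP signalling. It was 0.674 for embryonic and myogenic genes, 0.749 for slow fibre genes, 0.765 for polyamine metabolism, 0.786 for endoplasmic reticulum chaperones, 0.798 for Schwann cell markers and 0.996 for glycolysis, macrophage, satellite cell and erythroid lists. In the embryonic, slow fibre, glycolysis, macrophage and satellite cell lists the median and the mean differed in sign.

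**Figure D3:**
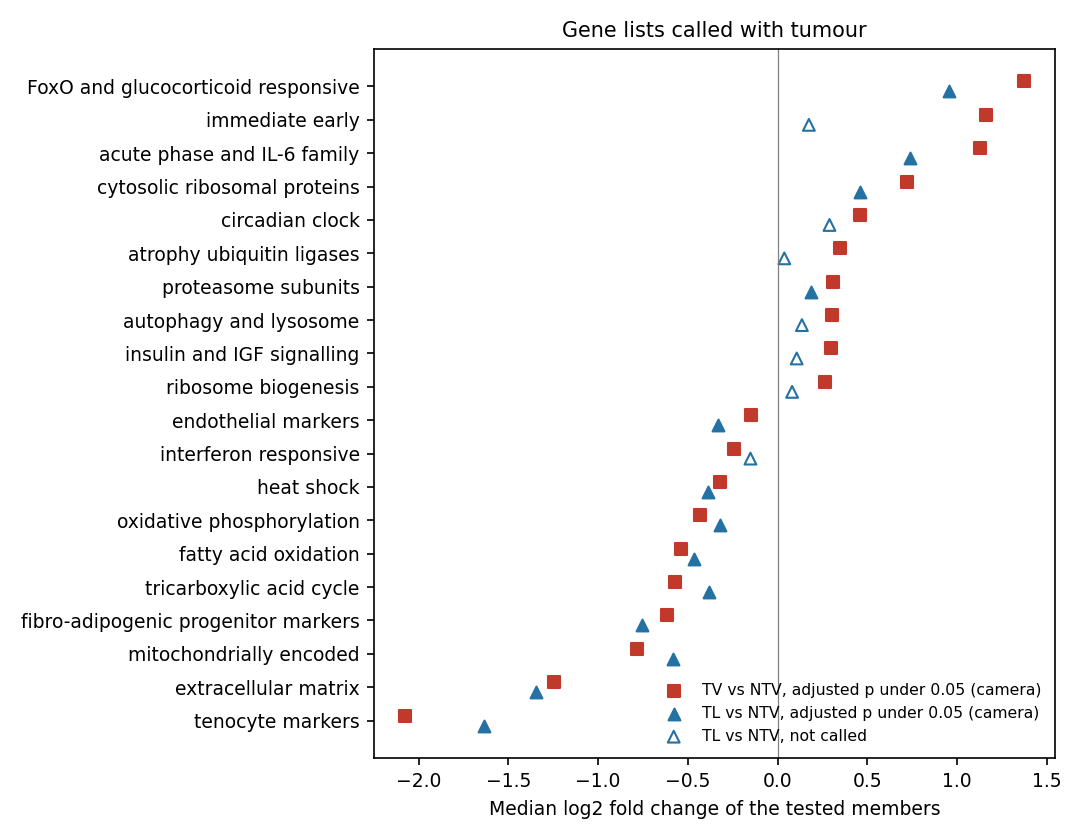
Median log2 change (x axis) of the tested members of each gene list called in TV against NTV (y axis), for TV against NTV (squares) and TL against NTV (triangles, open where camera did not call the list). Medians for TV against NTV run from -2.08 for tenocyte markers to 1.38 for FoxO and glucocorticoid responsive genes; no list was called with an estimated correlation.

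Several genes of interest to muscle wasting were not called in TV against NTV. Mstn, which encodes the growth inhibitor myostatin, differed by 0.25 ± 0.26 (adjusted p = 0.528), Pdk4, a kinase that restrains pyruvate oxidation, by 0.76 ± 0.84 (adjusted p = 0.539), the coactivator Ppargc1a by 0.37 ± 0.30 and the mitochondrial carrier Ucp3 by 0.02 ± 0.47. Of the myosin heavy chain genes, Myh2 differed by -1.16 ± 0.41 (adjusted p = 0.0562), Myh1 by 0.41 ± 0.32, Myh4 by 0.45 ± 0.22 and Myh7 by 0.65 ± 0.60. With 1 library left out, Mstn ranged from 0.039 (without TV replicate 6) to 0.39 and Pdk4 from 0.14 (without NTV replicate 2) to 1.39 (without TV replicate 6). Ppargc1a ranged from 0.11 to 0.66, Ucp3 from -0.41 to 0.43, Myh1 from 0.22 to 0.67, Myh4 from 0.29 to 0.58 and Myh7 from 0.27 to 1.31. Foxo1 rose by 1.31 ± 0.40 (adjusted p = 0.0343), a call that ended when any 1 of the 4 NTV libraries or TV replicate 3, 4 or 8 was left out (up to 0.093). It also ended with no filter and without the libraries with Ucp1 above 2 FPKM. Myh2 was called with the adipocyte covariate, with only the 2 groups compared and without mitochondrial and the 50 most abundant genes, and Myh7 without TV replicate 6.

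The target of the drug was weakly expressed in muscle. Ret averaged 1.04 ± 0.246 FPKM in NTV and 0.561 ± 0.127 in TV (-0.53 ± 0.17, adjusted p = 0.0359), and 0.648 ± 0.186 in TL (adjusted p = 0.803 against TV and 0.123 against NTV). With 1 library left out, the difference of TL from TV ranged from 0.029 to 0.23. The call of Ret ended without NTV replicate 2 or 5 or TV replicate 3, 4 or 6 (up to 0.0957). It also ended with no filter, rescaled to an equal total and without the libraries with Ucp1 above 2 FPKM. Gfral had 0 reads in all 12 libraries, which allows a level of up to 0.104 FPKM, and Gdf15 did not exceed 0.377 FPKM in any library. The list of the RET and GDF15 axis was not tested because only 4 of its 11 members passed the filter; the same held for neutrophil (4 of 15), lymphocyte (1 of 12) and proliferation (4 of 19) lists.

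The comparison of TL with TV asked what selpercatinib changed in tumour-bearing mice. Pnpla3, a lipid droplet protein with acyltransferase and lipase activity, rose by 2.85 ± 0.43 (adjusted p = 0.016) to 15.5 ± 4.25 FPKM. Myod1, the master regulator of myogenic differentiation, rose from 11.7 ± 4.2 to 37.2 ± 3.45 FPKM (1.69 ± 0.28, adjusted p = 0.0233). Mamstr, a muscle coactivator of MEF2, rose by 1.95 ± 0.28 (adjusted p = 0.0157) and Inka2, an inhibitor of the kinase PAK4, rose from 1.46 ± 0.405 to 5.02 ± 0.822 FPKM (adjusted p = 0.00409). Pfkfb3, which makes the glycolytic activator fructose bisphosphate, fell from 134 ± 24.1 to 25.2 ± 17.6 FPKM (-2.62 ± 0.41, adjusted p = 0.0197). The circadian repressors Nr1d1, which encodes REV-ERB alpha, and Ciart fell by 2.25 and 2.29 on the log2 scale (adjusted p = 0.0206 and 0.0364), Nr1d1 from 38.8 ± 21.6 to 7.01 ± 2.14 FPKM. Limma called 66 genes, 30 higher and 36 lower in TL, 22 of them by at least 2-fold. An unadjusted p under 0.05 was reached by 2057 genes. The fit takes 1 spread per gene from all 12 libraries. Pairs of NTV libraries differed less (chi-square per degree of freedom 16.4 to 27.7) than pairs of TV libraries (43.9 to 110.9). The NTV libraries, not part of this comparison, may thus make its SEs too small. With only the 2 groups compared, which also leaves fewer degrees of freedom, limma called 8 genes here and 1295 in TL against NTV. For 7.42% of tested genes the TL and TV values did not overlap, where chance gives 2.86%. Without TL replicate 5 the count was 7 and without TL replicate 1 it was 12, whereas it was 282 without TL replicate 4; it was 22, 24, 110 and 28 without TV replicate 3, TV replicate 4, TV replicate 6 and TL replicate 7. Of the genes named here, only Inka2 kept its call in every such fit (adjusted p up to 0.0213); Nr1d1 and Mamstr lost it without TL replicate 1 or 5 (up to 0.0857), Pnpla3 also without TV replicate 4, and Pfkfb3 also without TV replicate 3 or 4. Myod1 lost it without TV replicate 3 or 4 or TL replicate 1, 5 or 7, and Ciart when any 1 of these or TV replicate 6 or 8 was left out (up to 0.138). With only the 2 groups compared, Pnpla3, Mamstr, Myod1, Pfkfb3 and Nr1d1 lost the call, and with no filter Pnpla3, Myod1, Pfkfb3, Nr1d1 and Ciart did. Ciart lost it also with a pseudocount of 0.1, rescaled to an equal total and with the adipocyte covariate, and all 7 genes named here lost it without the libraries with Ucp1 above 2 FPKM. The change of Pnpla3 TL vs TV was 2.54 without these libraries. Over all settings Mamstr stayed between 1.72 and 2.30, Myod1 between 1.48 and 2.03 and Inka2 between 1.29 and 1.85. Pfkfb3 stayed between -3.05 and -1.84, Nr1d1 between -2.51 and -1.86 and Ciart between -2.74 and -1.96.

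**Figure D4:**
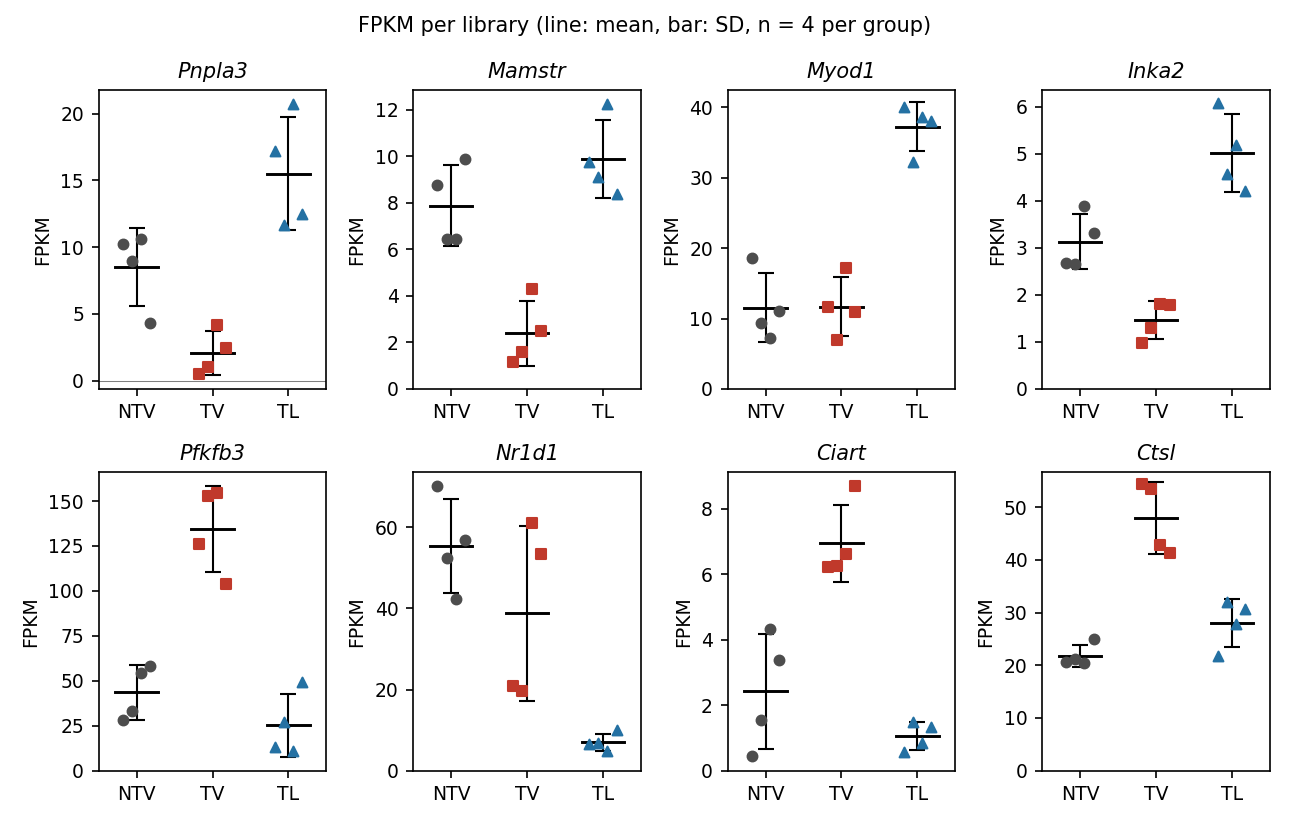
FPKM (y axis) of 8 genes called in TL against TV in each library of NTV, TV and TL (x axis), with the mean as a line and the SD as a bar (n = 4 per group). TL and TV values did not overlap in any of the 8; Myod1 averages 37.2 FPKM in TL and 11.7 in TV, and Pfkfb3 averages 25.2 and 134.

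Other genes called in TL against TV were Ifit3b, an interferon-induced gene with a near-identical copy (1.39 ± 0.25), and Ahdc1 (1.21 ± 0.20), which rose. Falls were called for the sodium-calcium exchanger Slc8a1 (-1.33 ± 0.23), the transcription factor Klf11 (-1.27 ± 0.21), the amino acid transporter Slc43a1 (-1.18 ± 0.17) and the lysosomal protease Ctsl (48.0 ± 6.87 to 28.1 ± 4.54 FPKM, -0.77 ± 0.14). All of these lost the call without TL replicate 1, without TL replicate 5 (adjusted p up to 0.127), with only the 2 groups compared and without the libraries with Ucp1 above 2 FPKM. With no filter all but Slc43a1 lost it, rescaled to an equal total Slc8a1, Klf11 and Ctsl, with quantile normalization Ctsl, and with the adipocyte covariate Ifit3b. Over all settings the change nearest to 0 was 1.15 for Ifit3b, 1.09 for Ahdc1, -1.11 for Slc8a1, -0.95 for Klf11, -1.06 for Slc43a1 and -0.60 for Ctsl. Klf11, Ahdc1, Ctsl, Slc8a1 and Ifit3b lost it also without TV replicate 3 or 4, the last 4 of these without TL replicate 7, and Slc8a1 and Ifit3b without TV replicate 8. Trim63, Fbxo32, Cebpd and Mt1, which were higher in TV than NTV, were not called in TL against TV. Trim63 averaged 111 ± 81.1 FPKM in TL and 405 ± 295 in TV (-1.91 ± 0.56, adjusted p = 0.148), with 43.5, 215, 49.4 and 134 FPKM in TL replicates 1, 4, 5 and 7. Fbxo32 averaged 55.4 ± 42.2 and 187 ± 106 FPKM (-1.87 ± 0.54, adjusted p = 0.146). Cebpd differed by -1.52 ± 0.69 (adjusted p = 0.305), Mt1 by -2.10 ± 0.68 (adjusted p = 0.177), Pdk4 by -2.01 ± 0.84 (adjusted p = 0.268) and Mstn by -0.49 ± 0.26 (adjusted p = 0.389). Foxo1 (-0.59 ± 0.40), Mt2 (-0.55 ± 0.89), Fkbp5 (-0.13 ± 0.47), Ucp3 (-0.81 ± 0.47) and Ppargc1a (-0.29 ± 0.30) were not called either. Neither were Myh1 (-0.21 ± 0.32), Myh2 (-0.10 ± 0.41), Myh4 (-0.28 ± 0.22) and Myh7 (0.37 ± 0.60). Without TL replicate 4, Fbxo32 (adjusted p = 0.0423) and Mt1 (0.044) were called, Fbxo32 also with library weights. With 1 library left out, Mstn ranged from -0.72 to -0.28, Foxo1 from -0.95 to -0.37, Mt2 from -1.16 to -0.0034 (without TV replicate 3), Ucp3 from -1.21 to -0.49 and Ppargc1a from -0.59 to -0.038 (without TV replicate 3). Fkbp5 ranged from -0.42 to 0.12, Myh2 from -0.43 to 0.13, Myh7 from -0.29 to 0.75, Myh1 from -0.47 to -0.013 and Myh4 from -0.41 to -0.11.

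Except for autophagy and lysosome genes, no list called in TL against TV had a called member. The 73 ribosomal protein genes had a median of -0.25 (0 called; 0 adjusted over the list alone; adjusted p = 0.673 with an estimated correlation), with the lowest p for Rpl7a (-0.90 ± 0.20, adjusted p = 0.0725). The 25 FoxO and glucocorticoid responsive genes had a median of -0.55 (0 called; 7 lower adjusted over the list alone; adjusted p = 0.66 with an estimated correlation), as for Sesn1 (-1.21 ± 0.26, adjusted p = 0.0717). The 20 immediate early genes had a median of -0.69 (0 called; 2 lower adjusted over the list alone; adjusted p = 0.66 with an estimated correlation), with Maff at -2.47 ± 0.50 (adjusted p = 0.057) and Junb at -1.89 ± 0.44 (adjusted p = 0.0838). Acute phase genes had a median of -0.38 (0 called; 2 lower adjusted over the list alone; adjusted p = 0.66 with an estimated correlation), with Stat3 at -0.78 ± 0.17 (adjusted p = 0.0719), and a median of -0.11 without TV replicate 3, where the list was not called (adjusted p = 0.106). Fast fibre genes had a median of -0.28 (0 of 18 called; 3 lower adjusted over the list alone; adjusted p = 0.673 with an estimated correlation), with Mybpc2 at -0.69 ± 0.17 and Mylk2 at -0.65 ± 0.17. Sarcomere and Z-disc genes had a median of -0.23 (0 of 27 called; 0 adjusted over the list alone; adjusted p = 0.66 with an estimated correlation), with Des at -0.57 ± 0.17; the median was -0.37 without TV replicate 6. Atrophy ubiquitin ligases had a median of -0.14 (0 of 18 called; 4 lower adjusted over the list alone; adjusted p = 0.66 with an estimated correlation), with Nedd4 at -0.47 ± 0.12. Without TV replicate 3 or 4 the ligase list was not called (up to 0.0755; median -0.062 without TV replicate 4), and neither was the fast fibre list without TV replicate 6 or 8 (up to 0.137; medians from -0.42 without TV replicate 3 to -0.17 without TV replicate 8). Without TL replicate 4, Rpl7a, Sesn1, Maff, Junb, Stat3, Mybpc2, Des and Nedd4 were called, and with library weights all of these but Des. Sesn1, Maff and Stat3 were also called without TV replicate 6, and Sesn1 and Nedd4 without TV replicate 8. Maff was called as well with a mean FPKM of at least 1, a pseudocount of 1 and voom on recovered reads.

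Camera called 5 other lists lower in TL than TV. Insulin and IGF signalling had a median of -0.29 (0 of 19 called; 0 adjusted over the list alone; adjusted p = 0.66 with an estimated correlation), with Irs2 at -1.91 ± 0.63, and was not called without TV replicate 3 (adjusted p = 0.0987). Autophagy and lysosome genes had a median of -0.22 (1 of 27 called, Ctsl; 3 lower adjusted over the list alone; adjusted p = 0.66 with an estimated correlation). Proteasome subunits had a median of -0.13 (0 of 32 called; 0 adjusted over the list alone; adjusted p = 0.759 with an estimated correlation), with Psmd8 at -0.67 ± 0.18; the median was -0.23 without TL replicate 4 and -0.077 without TL replicate 1. Ribosome biogenesis had a median of -0.10 (0 of 24 called; 0 adjusted over the list alone; adjusted p = 0.66 with an estimated correlation), with Npm1 at -0.33 ± 0.10, and was not called without TV replicate 3 or 8 or TL replicate 5 (up to 0.106). Endoplasmic reticulum chaperones had a median of -0.13 (0 of 17 called; 0 adjusted over the list alone; adjusted p = 0.673 with an estimated correlation), with Calr at -0.41 ± 0.14. The chaperone list was not called without TV replicate 3 or 8 or TL replicate 1 or 5 (up to 0.128), and its median was -0.22 without TL replicate 4. Quantile normalization ended the calls of proteasome, atrophy ligases, fast fibre, chaperones and ribosome biogenesis in TL against TV. Rescaling to an equal total, and leaving out mitochondrial and the 50 most abundant genes, each ended those of chaperones and ribosome biogenesis. The chaperone call also ended with a mean FPKM of at least 1 and the fast fibre call with no filter. Psmd8 was called without TL replicate 4 and with library weights.

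Of the members nearest to the threshold, Scd2 and Sc5d of sterol and fatty acid synthesis were at 1.26 ± 0.46 and 0.45 ± 0.18 in TL against TV. Dlat and Dld of the tricarboxylic acid cycle were at 0.51 ± 0.17 and 0.35 ± 0.13, and Ndufb2 and Ndufs1 of complex I at 0.44 ± 0.15 and 0.48 ± 0.16; none was called. Lists higher in TL than TV were fatty acid and sterol synthesis (median 0.37; 0 of 28 called; 0 adjusted over the list alone; adjusted p = 0.66 with an estimated correlation), the tricarboxylic acid cycle (0.17; 0 of 22; 0 adjusted over the list alone; 0.759) and oxidative phosphorylation (0.11; 0 of 74; 0 adjusted over the list alone; 0.775). The lipid genes were uneven between TL libraries: the desaturase gene Scd1 measured 318, 17.8, 680 and 21.8 FPKM in TL replicates 1, 4, 5 and 7, and Fasn, fatty acid synthase, 137, 14.9, 121 and 3.66 FPKM. In the same libraries the mean log2 difference from NTV was 1.07, -0.13, 1.21 and -0.19 for fatty acid and sterol synthesis and 1.92, 0.55, 2.31 and -0.20 for adipocyte markers. In NTV replicate 5 these values were 0.50 and 1.14. Ucp1, the brown fat uncoupling protein, measured 53.4 FPKM in NTV replicate 5, 58.3 in TL replicate 1 and 3.97 in TL replicate 5. Without TV replicate 3 or TL replicate 5, oxidative phosphorylation was no longer called (medians of 0.018 and 0.0072) and neither was the tricarboxylic acid cycle (0.12 and 0.077). Without TL replicate 4 the 2 medians were 0.22 and 0.28. Scd2 was called without TL replicate 4.

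The 30 extracellular matrix genes had a median of -0.22 in TL against TV (0 called; 3 lower adjusted over the list alone; adjusted p = 0.759 with an estimated correlation), with Thbs1 at -1.37 ± 0.31 (adjusted p = 0.0769) and Mmp14 at -0.67 ± 0.16. Without TL replicate 4 this median was -0.012, and the list was not called (adjusted p = 0.337); the same held without TV replicate 8, and the median was -0.41 without TV replicate 4. Nor was it called with library weights. Circadian clock genes missed the threshold (adjusted p = 0.0548, median -0.29; Nr1d1 and Ciart called; 2 higher and 4 lower adjusted over the list alone), as did smooth muscle and pericyte markers (adjusted p = 0.0941). In this comparison camera called 16 of 37 lists, 3 higher and 13 lower. An estimated correlation called 0 (0 at an unadjusted p under 0.05), fry 0 (6 at an unadjusted p under 0.05), and the exact permutation of list means 0 (3 at its smallest p of 0.0286). When the libraries with Ucp1 above 2 FPKM (NTV replicate 5, TL replicates 1 and 5) were left out, which keeps 2 TL libraries, limma called 0 genes in TL against TV (908 at an unadjusted p under 0.05) and camera 8 lists, 5 of them among the 16. With all libraries and the mean of the adipocyte markers as covariate, limma called 54 genes, 46 of them among the 66, and of the 16 lists only chaperones lost the call. Both alternatives were chosen after the data were seen. Voom on the recovered reads of all libraries called 75 genes. The lists no longer called without those 3 libraries were ribosomal proteins, ribosome biogenesis, proteasome, FoxO and glucocorticoid responsive, immediate early, atrophy ligases, insulin signalling, endoplasmic reticulum chaperones, fatty acid and sterol synthesis, oxidative phosphorylation and the tricarboxylic acid cycle; the last 2 had medians of -0.075 and -0.033.

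**Figure D5:**
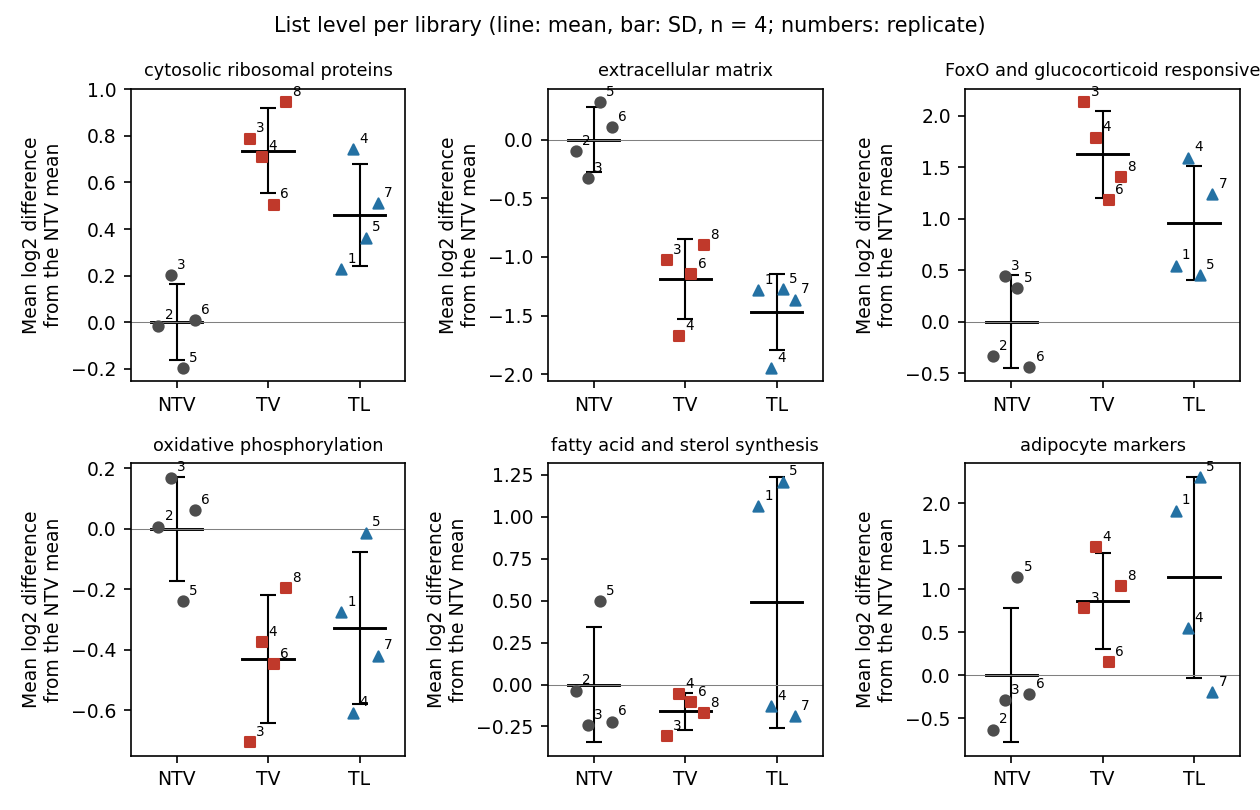
Mean log2 difference of a list's genes from the NTV mean (y axis) in each library of NTV, TV and TL (x axis, replicate number beside each point), with the group mean as a line and the SD as a bar (n = 4 per group). All TV and TL values lie above the NTV mean for ribosomal proteins and below it for extracellular matrix genes, while TL replicates 1 and 5 lie above the other TL libraries for fatty acid and sterol synthesis.

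TL was also compared with NTV, that is, treated tumour-bearing with tumour-free mice. Prima1, which anchors acetylcholinesterase to membranes, rose from 2.64 ± 1.38 to 17.1 ± 4.39 FPKM (2.56 ± 0.29, adjusted p = 0.00191), and Tmem100 rose by 2.38 ± 0.45. Col1a1 fell from 25.8 ± 10.9 to 1.90 ± 0.882 FPKM (-3.45 ± 0.40), and Col3a1 and Kera changed by -3.26 ± 0.40 and -3.17 ± 0.47. Fkbp5 was higher by 2.29 ± 0.47 (adjusted p = 0.015), while Trim63 (0.21 ± 0.56, adjusted p = 0.844) and Fbxo32 (-0.08 ± 0.54, adjusted p = 0.945) were not called. Without TL replicate 4 these values were -0.21 and -0.53, and without TL replicate 1 they were 0.55 and 0.37. Ctxn3 was higher by 2.41 ± 0.58 (adjusted p = 0.0257). Limma called 1123 genes, 534 higher and 589 lower in TL, 227 of them by at least 2-fold; the 2 groups did not overlap for 20.8% of tested genes, where chance gives 2.86%. The count was 514 without TL replicate 4, 536 without TL replicate 7, and 612, 711, 539 and 563 without NTV replicates 2, 3, 5 and 6. The call of Ctxn3 ended without NTV replicate 2, 3 or 5 or TL replicate 4 or 7 (adjusted p up to 0.0691), and also with no filter and with voom on recovered reads.

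Of 30 extracellular matrix genes, 23 fell and 0 rose in TL against NTV, with a median of -1.35 (28 lower adjusted over the list alone; adjusted p = 0.548 with an estimated correlation). Called members included the basement membrane collagen Col4a2 (-1.90 ± 0.20). Of 9 tenocyte markers 6 fell (median -1.64; 8 lower and 1 higher adjusted over the list alone), and of 12 fibro-adipogenic progenitor markers 3 fell (-0.76; 4 lower adjusted over the list alone), including Serpinf1 (-1.84 ± 0.30); without TL replicate 4 the latter median was -0.44. Of 73 ribosomal protein genes 16 rose (median 0.46; 53 higher adjusted over the list alone), of 25 FoxO and glucocorticoid responsive genes 7 rose (0.96; 12 higher), including Glul (1.27 ± 0.24), and of 18 acute phase genes 4 rose (0.74; 9 higher), including Il6ra (2.08 ± 0.38). Falls were called for 6 of 74 oxidative phosphorylation genes (median -0.32; 2 adjusted over the list alone), 3 of 22 tricarboxylic acid cycle genes (-0.38; 10), 3 of 34 fatty acid oxidation genes (-0.47; 12), including Fabp3 (-1.93 ± 0.31), and 1 of 13 mitochondrially encoded genes (-0.58; 1), which was mt-Atp6 (-1.57 ± 0.21). The mitochondrially encoded median was -0.34 without TL replicate 4 and -0.39 without TL replicate 7. For each of these lists the adjusted p was 0.548 with an estimated correlation.

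Further lists called in TL against NTV were heat shock (3 of 16 fell, including Hsph1 at -1.03 ± 0.16; 6 lower adjusted over the list alone), endothelial markers (3 of 15 fell, including Cldn5 at -0.66 ± 0.13; 3 lower), smooth muscle and pericyte markers (2 of 11 fell; 3 lower) and endoplasmic reticulum chaperones (2 of 17 fell, including Pdia3 at -0.51 ± 0.10; 2 lower), with an adjusted p of 0.548 with an estimated correlation. Proteasome subunits had a median of 0.19 with 0 of 32 called (0 adjusted over the list alone; adjusted p = 0.698 with an estimated correlation), Psmd8 at 0.52 ± 0.18 (adjusted p = 0.0846), and a median of 0.099 without TL replicate 4. Adipocyte markers had a median of 0.97 with 0 of 13 called (3 higher adjusted over the list alone; adjusted p = 0.548 with an estimated correlation), Retn at 1.95 ± 0.62 (adjusted p = 0.0713), and were not called without the Ucp1-expressing libraries; the same held for smooth muscle markers and chaperones. These 3 lists were not called in TV against NTV (adjusted p = 0.0818, 0.226 and 0.786). Atrophy ubiquitin ligases were not called (adjusted p = 0.436, median 0.04). Of the ribosome biogenesis list, not called (adjusted p = 0.103), Nop56 was called at 0.35 ± 0.09, and of the denervation list, not called (adjusted p = 0.104), Myog, a myogenic transcription factor, at 1.28 ± 0.31 and Hdac9 at -0.84 ± 0.22. All 3 calls ended without NTV replicate 2 or 5 or TL replicate 7, that of Nop56 also without NTV replicate 3 or TL replicate 1, that of Myog also without NTV replicate 6 or TL replicate 4, and that of Hdac9 when any 1 of these was left out (adjusted p up to 0.0983). Without the Ucp1-expressing libraries the calls of Cldn5, Nop56 and Hdac9 ended, with no filter those of Myog and Hdac9, with the adipocyte covariate that of Hdac9, and rescaled to an equal total that of Pdia3. Mt1 (1.85 ± 0.68, adjusted p = 0.102), Mt2 (2.79 ± 0.89, adjusted p = 0.0699), Cebpd (1.18 ± 0.69), Foxo1 (0.72 ± 0.40), Pdk4 (-1.26 ± 0.84) and Myh2 (-1.26 ± 0.41, adjusted p = 0.0748) were not called. With 1 library left out, Foxo1 ranged from 0.36 to 0.91, Cebpd from 0.73 to 1.57 and Pdk4 from -1.88 to -0.83. The endothelial median was -0.22 without NTV replicate 5, and the chaperone list was not called without NTV replicate 2, 5 or 6 or TL replicate 1 or 5 (adjusted p up to 0.132), with a median of -0.14 without NTV replicate 6. Neither was it called rescaled to an equal total, without mitochondrial and the 50 most abundant genes, without the trend, with only the 2 groups compared or with the adipocyte covariate. Camera called 16 lists, 5 higher and 11 lower; fry called 3, and an estimated correlation and the exact permutation of list means each called 0 (1 and 7 at an unadjusted p under 0.05). Myh2 was called with the adipocyte covariate, without the Ucp1-expressing libraries and without TL replicate 1. Calls were also gained by Retn with library weights and without TL replicate 7, and by Mt1 and Psmd8 without TL replicate 5.

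The tumour and drug comparisons were then set side by side. No tumour-free group received selpercatinib. A drug effect unrelated to the tumour therefore cannot be told apart from a loss of the tumour change. Of the 3217 genes called in TV against NTV, 47 were called in the opposite direction in TL against TV and 0 in the same direction. These were 31 genes that rose with the tumour and were lower in TL, where independent lists would share 4.95, and 16 that fell and were higher in TL, where they would share 3.44. Both comparisons use the TV libraries, so chance alone favours opposite directions. Of the 47, 5 were called past the NTV level: Pdzrn3, Etl4, Tnfrsf19, Inka2 and Gm45819. In TL against NTV these 5 were called in the direction opposite to the tumour change, as for Inka2 (0.60, adjusted p = 0.0462 by limma). Estimates of other genes also lay past the NTV level without a call, such as Pfkfb3 (-0.96) and Pnpla3 (0.87) in TL against NTV. Others stopped short of it, such as Ctsl (0.35). Among the 47 were Eef2, the translation elongation factor (0.79 in TV against NTV and -0.79 in TL against TV), Ddi2, an aspartic protease (1.29 and -1.09), Ctsl (1.12 and -0.77), Slc43a1 (1.71 and -1.18), Pfkfb3 (1.67 and -2.62), Ciart (1.59 and -2.29), Pnpla3 (-1.99 and 2.85) and Mamstr (-1.64 and 1.95). The count was 6 without TL replicate 5, 10 without TL replicate 1 and 222 without TL replicate 4, and it was 19, 18, 85, 71 and 24 without TV replicates 3, 4, 6 and 8 and TL replicate 7. It was 0 without the Ucp1-expressing libraries and 39 with the adipocyte covariate. When the TV libraries were divided into 2 and 2, so that each comparison used its own, the count averaged 23.7 over 6 divisions (1 to 116).

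Across the 12754 genes, which are not independent replicates, the log2 changes in TV against NTV and TL against TV had a Pearson r of -0.56. Unchanged groups that share the TV libraries gave -0.50 (SD 0.0192, 100 simulations), and with the TV libraries divided the mean r was -0.30 (-0.38 to -0.12). The simulation gave a gene the same spread in all groups and drew genes independently. Pairs of TV libraries differed more (chi-square per degree of freedom 43.9 to 110.9) than pairs of NTV libraries (16.4 to 27.7). The simulated SD therefore does not measure how far r can go by chance. The covariance was -0.0943, against -0.0297 in the simulation, a difference of -0.0646, and -0.0607 with the TV libraries divided. In TL against NTV, 885 of the 3217 genes were called in the same direction as in TV against NTV (404 higher and 481 lower, where independent lists would share 73.5 and 67.5) and 5 in the opposite direction. The shared NTV libraries add to this overlap: r between these changes was 0.76, 0.50 in the simulation and 0.58 with the NTV libraries divided; the covariance was 0.164, against 0.0295 in the simulation. The median share of the tumour change that remained in TL was 62.8% over the 3217 genes, 57.8% for those that rose and 69.0% for those that fell. When 1000 genes were chosen with 2 TV and 2 NTV libraries and measured with the other 4 and TL, the median over 36 divisions was 65.7% (55.5% to 87.6%). Without the Ucp1-expressing libraries the share was 83.0%, with the adipocyte covariate 69.8%, and without TL replicate 5 and TL replicate 4 it was 71.0% and 52.6%.

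Positions are those listed with the values, for build mm10, and values cover whole genes, not exons or untranslated regions. Trim63 (ENSMUSG00000028834) lies on chromosome 4 from 134315120 to 134329629, Fbxo32 (ENSMUSG00000022358) on chromosome 15 from 58175879 to 58214932, Mt1 (ENSMUSG00000031765) on chromosome 8 from 94179082 to 94180327 and Col1a1 (ENSMUSG00000001506) on chromosome 11 from 94936224 to 94953042. Kera (ENSMUSG00000019932) lies on chromosome 10 from 97606879 to 97613692, Fabp3 (ENSMUSG00000028773) on chromosome 4 from 130308595 to 130315463, Pnpla3 (ENSMUSG00000041653) on chromosome 15 from 84167837 to 84187236, Nr1d1 (ENSMUSG00000020889) on chromosome 11 from 98767932 to 98775333 and Ret (ENSMUSG00000030110) on chromosome 6 from 118151745 to 118197718.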

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

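Of the tests in this part, the comparison with lists of other cell types, the adipocyte covariate and the comparison with tenocyte markers were chosen after the result was seen. A library was singled out where it lay far from the other 3 of its group, by the gap to the nearest value relative to the range. Of 390 groups of gene values 9 met this rule, where 19.5 would by chance, of 111 groups of list means 7, where 5.55 would, and of 6 library totals 0. TL replicate 4 holds 7 of the 16 values.

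In TL replicate 4, the FoxO factor Foxo3 measured 12.2 FPKM (7.34 to 7.79 in the other TL libraries), Nedd4, a ubiquitin ligase, 59.7 (48.1 in the others) and Ret 0.373 (0.696 to 0.772). Its mean log2 difference from NTV was 0.87 for denervation responsive genes, -1.95 for extracellular matrix, -0.41 for macrophage markers and -1.27 for fibro-adipogenic progenitor markers. In TL replicate 1, heat shock genes lay at -0.070. In TV replicate 4, Col3a1 measured 0.718 FPKM (2.89 to 3.32 in the other TV libraries) and Klf11 4.55 (3.70 to 3.77), and immediate early genes lay at 0.63. In TV replicate 6, mt-Atp6 measured 185 FPKM (269.6 to 288.7) and Psmd7 70.8 (89.3 to 91.0), and in TV replicate 3 Cycs measured 47.7 (58.7 to 61.3). In NTV replicate 3, Nolc1 measured 6.21 FPKM (7.21 to 7.33), and in NTV replicate 5 acute phase genes lay at 0.36.

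Ribosomal protein genes were higher in TV than NTV, with a median log2 change of 0.72. After a trend with gene length, GC content and abundance was removed the median was 0.67 (SE 0.0884), which argues against that bias as the whole cause. Genes with the fewest pseudogenes annotated under their name (0 to 1, 34 genes) had a median of 0.78 (SE 0.121), and those with the most (27 genes) 0.65. That argues against reads of the pseudogenes counted. Pseudogenes annotated under other names were not counted, so reads of those stay open. A larger share of other cell types in the muscle would raise their markers alike. The medians of 5 of 5 lists (endothelial, macrophage, fibro-adipogenic, smooth muscle and Schwann) lay at or below 0. Mean differences were -0.65 (SE 0.179) for fibro-adipogenic, -0.24 (SE 0.131) for endothelial and -0.28 (SE 0.224) for smooth muscle markers. These 3 argue against a rise in such cells like that of the ribosomal protein genes. For macrophage (0.027, SE 0.286) and Schwann markers (-0.11, SE 0.344) the spread was too wide to tell. Adipocyte markers, not among the 5, had a median of 0.54 (adjusted p = 0.0818 by limma's camera); with adipocyte markers as covariate the median of cytosolic ribosomal proteins TV vs NTV was 0.87, not nearer to 0, which argues against more fat cells as the whole cause.

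Extracellular matrix genes were lower in TV and TL than in NTV. With fewer fibroblasts in the piece of muscle, the 6 progenitor markers that are not matrix genes would fall alike, but their median lay above that of the matrix list by 0.78 (SE 0.153) in TV and 0.77 (SE 0.136) in TL. That argues against fewer fibroblasts as the whole cause only if other cells do not make these markers, which was not tested. All 6 had negative changes in both comparisons, and they were uneven. Pi16 fell in TV by more than the matrix median (-1.57 against -1.24). Cd34 fell in TV (-0.90) and in TL (-1.02, adjusted p = 0.00634 by limma), so a partial loss stays open. Less tendon in the piece may account for part of the pattern, since tenocyte markers lay below the matrix list by a median difference of -0.83 (SE 0.284) in TV and -0.29 (SE 0.370) in TL; most of these markers encode matrix proteins, so lower expression per cell would look the same, and the transcription factor Scx was higher in TV (1.12 ± 0.38, not called). With the length, GC and abundance trend removed the median was -1.25 (SE 0.191) in TV against NTV, which argues against that bias.

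Nr1d1 and Ciart were lower in TL than TV. If the tissues had been taken at different times of day, the other clock genes would differ according to their phase. None of the 9 tested was called (smallest adjusted p = 0.0992 by limma, Cry1), but 8 had the sign this predicts, all but Hlf (0.61 ± 0.18, adjusted p = 0.148), with a median signed log2 change of 0.42 (SE 0.0848), so a difference in sampling time may account for part of it. In TV against NTV these genes had the mirrored sign, all but Dbp (-0.52), as for Per3 (0.77), Tef (0.49), Arntl (-0.52) and Clock (-0.43). Of these only Tef was called (adjusted p = 0.0414 by limma). The same limit therefore holds for the rise of clock genes in TV against NTV. The labels give no time of sampling, and a shift of the internal clock would look the same. With any 1 library left out, at least 87.7% of the difference was left, which argues against 1 library deciding its size. Both genes were named for large changes without overlap between groups, which favours this outcome. The calls of both ended in some of these fits.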

How the results depend on the processing

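Of the alternatives, voom on reads, the Ucp1 omission, the adipocyte covariate, the exact permutation and the divided-library share were chosen after the data were seen. Outside the fits that left out 1 library, 2815 gene values kept their direction and their side of the threshold, 184 became weaker, 26 stronger and 24 changed sign; for lists 791 kept them, 138 became weaker and 4 changed sign. Except with the replicate number as a block, genes called in TV against NTV stayed within 1.5 times of 3217 (2217 to 3985). For the values below the cause was not tested.

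In TL against TV, limma called 66 genes; 19 with no filter, 38 with libraries rescaled to an equal total, 232 with library weights, 8 with only the 2 groups compared, 0 without the Ucp1 libraries (2 in TL), 54 with the adipocyte covariate (46 of them among the 66), and from 7 (without TL replicate 5) to 282 (without TL replicate 4). In TL against NTV the 1123 genes were 742 with no filter, 718 rescaled, 712 without the Ucp1 libraries and from 514 to 1160 with 1 library left out. The share of calls that were higher went from 54.6% to 37.1% without mitochondrial and the 50 most abundant genes in TV against NTV. It went from 45.5% to 76.3% rescaled and 63.5% without those genes in TL against TV, and from 47.6% to 64.3% rescaled in TL against NTV. The 20, 16 and 16 lists called were 0, 0 and 0 with an estimated correlation and by exact permutation, and 18 (17 of the 20), 0 and 3 by fry. TL against TV gave 8 lists (5 of the 16) without the Ucp1 libraries, 15 with the covariate, 12 (11 of the 16) with quantiles and 10 to 21 with 1 library left out. The 0 calls by exact permutation say little. With 4 against 4 libraries its p cannot go under 0.0286. After adjustment over 37 lists it can call a list only if many lists reach that p.

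Genes moved back, 47, were 15 with no filter, 25 rescaled, 185 with weights, 6 with only the 2 groups, 0 without the Ucp1 libraries, 39 with the covariate, 23.7 with TV divided and 6 to 222 with 1 library left out. The reversal r of -0.56 was -0.63 with weights, -0.33 without the Ucp1 libraries, -0.52 with the covariate, -0.30 with TV divided and -0.63 to -0.47 with 1 library left out. The remaining share of 62.8% was 56.6% with weights, 83.0% without the Ucp1 libraries, 69.8% with the covariate and 52.6% to 71.0% with 1 library left out.

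These uncalled values changed sign. In TL against NTV, Fbxo32 was 0.41 with the covariate, 0.75 without the Ucp1 libraries and 0.056 rescaled; Mstn 0.16 and 0.047, Myh1 -0.12 and -0.38 and Ppargc1a -0.17 and -0.083 with the covariate and without the Ucp1 libraries; Trim63 -0.044 with weights. In TL against TV without the Ucp1 libraries, Fkbp5 was 0.19, Mt2 0.27, Ret -0.013 and Ighm -0.33. In TV against NTV, Ucp3 was -0.43 with the covariate, -0.0044 with median-of-ratios on the tested genes, -0.10 with quantiles and -0.081 without mitochondrial and abundant genes. With 1 library left out, Fbxo32 ranged from -0.53 to 0.37, Trim63 from -0.21 to 0.55 and Ppargc1a from -0.091 to 0.18 in TL against NTV. In TL against TV, Fkbp5 ranged from -0.42 to 0.12, Myh2 from -0.43 to 0.13, Myh7 from -0.29 to 0.75 and Ighm from -0.094 to 0.43, and in TV against NTV Ucp3 from -0.41 to 0.43. Of the lists called in TL against TV, oxidative phosphorylation was -0.075 and the tricarboxylic acid cycle -0.033 without the Ucp1 libraries.

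The labels name nothing shared by libraries of the same replicate number, and such libraries correlated at 0.0142, 0.133, 0.0861 and 0.0751; this does not exclude a shared cage or day. With the replicate block, 2 residual degrees of freedom remained, limma called 0 genes in each comparison (2711, 777 and 1422 at an unadjusted p under 0.05), 0 genes moved back and r was -0.48. In this block fit Pdk4 was -0.21 and Ucp3 -0.70 in TV against NTV; Ret -0.22, ribosomal proteins 0.054 and proteasome subunits 0.050 in TL against TV; Fbxo32 0.030, Myh1 -0.0745 and Ppargc1a -0.25 in TL against NTV.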

Other observations

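Gdnf and Ighm were chosen after their values were seen. Gdnf, a ligand of the RET receptor complex, rose from 0.251 ± 0.0852 FPKM in NTV to 1.56 ± 0.420 in TV (n = 4 per group; 1.44 ± 0.25, adjusted p = 0.00282 from limma). It measured 0.659 ± 0.453 FPKM in TL and was not called against TV (-0.89 ± 0.25, adjusted p = 0.135), except with library weights and without TL replicate 4. Ighm, the heavy chain of immunoglobulin M made by B cells, fell in TV, to 0.584 ± 0.241 FPKM (-3.30 ± 0.39, adjusted p = 0.000898) and 0.868 ± 0.729 in TL (-3.08 ± 0.39, adjusted p = 0.00235). The NTV libraries ranged from 5.18 to 15.6 FPKM of Ighm; SCID mice usually lack mature B cells, but the phenotype can be leaky. Both calls against NTV held in every fit that left out 1 library. Gdnf lies on chromosome 15 from 7810846 to 7837575 and Ighm on chromosome 12 from 113418558 to 113422730.

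Counts were repeated after the libraries of each comparison were divided into groups of 4 and 4 in all 35 ways. The count of genes called was reached by 1 of 35 divisions, the real one, in TV against NTV (at most 2 genes in any other), by 1 in TL against TV (at most 14) and by 1 in TL against NTV (at most 1). The count of lists called was reached by 6 of 35 in TV against NTV (up to 22 lists in another), 13 in TL against TV (up to 22) and 9 in TL against NTV (up to 20), so chance was not excluded for the list counts. Among 70 assignments of the TV and TL libraries, a count of genes moved back as large was reached by 1 (at most 18 in any other). A correlation as negative was reached by 5 (down to -0.68), and a remaining share as low by 4 (down to 57.0%), so chance was not excluded for these.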
